A study of Mus musculus with 10 samples.

How the data were processed

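Gene expression was measured by single-end RNA sequencing in retinal ganglion cells, the output neurons of the retina, of mice at postnatal day 6. The cells carried a green fluorescent protein reporter driven by Hb9 (Mnx1) and were collected by fluorescence-activated sorting, with RNA taken from about 1000 cells per sample, per the series' design text. Per the labels, 5 libraries came from wild-type mice and 5 from mice lacking Satb1, and the samples of each genotype came from different litters. Because so little RNA was at hand, the cDNA was amplified before library construction, per the labels' protocols. Amplification of this kind adds variation between libraries, and the share of a transcript can then depend on its length and base composition.

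The deposited table holds log10(TPM + 1) values for 23746 gene entries in the 10 libraries, made by the authors. The log base and the offset were read from the values: after back-transformation on base 10 and subtraction of 1, every library summed to 1000000 TPM, a transcript abundance scaled for transcript length and library total. TopHat2 2.0.10, Cufflinks and the mouse build mm10 are named in the submitters' processing notes. The counting step, the gene annotation, any filter and the use of strand are not given in the sources used here, so reads of overlapping genes, close paralogs and pseudogenes may be split or shared in ways that the values do not show. TPM keeps no depth, so the depth of each library is unknown and no interval or detection floor based on counts was computed. A value of exactly 0 can be a failed estimate: of 1100 genes with a median of at least 100 TPM, 8 were listed at 0 in at least 1 library, among them the tubulin gene Tuba1a, listed at 0 in knockout 4 and 5 and above 10000 TPM elsewhere. For genes listed at 0 in any library, single library values or their range are therefore given in place of a mean TPM.

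Entries with a number in place of a gene symbol (25, holding 0.044% to 0.2% of the TPM of a library) were left out, and 240 symbols found on more than 1 line were summed in TPM, which left 23259 symbols. Values were put on the log2(TPM + 1) scale. Fold changes are knockout minus wild-type on that scale, which understates the change of genes with low values. Genes with at least 1 TPM in at least 5 libraries were tested, 11745 in all. The test was limma 3.58.1 in R 4.3.3, with genotype as the only term, a mean-variance trend, and Benjamini-Hochberg adjustment at a threshold of 0.05. For single genes set in advance, a two-sided exact permutation test over the 252 divisions of the 10 libraries was added, whose smallest possible p is 0.00794. Gene lists were compared with all other tested genes by camera from limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, and were tested by fry. The 38 lists cover retinal cell types, cell types a sort can carry along, adhesion and guidance proteins, receptors and channels, chromatin proteins, and stress and metabolic genes. The 34 lists with at least 5 tested members entered the tests. Results for members of a list were also adjusted over the list alone.

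The groups, the test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The exact permutation test was planned for Satb1 and Cntn5 only. Its use for the other preset genes, the adjustment over the 9 and the adjustment over a list alone were not in that plan. The rule names 9 preset genes, up to 12 genes per direction, and the members with the smallest p of each list described. Not all of these list members are described below. Of the 9, Satb1, Mnx1, Cntn5, Cartpt, Mmp17, Col25a1, Cdh6 and Fstl4 are described; 1 preset gene and a few members of lists stayed in the tests but are not reported here. Genes past the threshold would have come first; none passed, so the 12 places per direction were filled in order of p, leaving out predicted genes, clones, microRNAs and small nucleolar RNAs. Cntn5 is known to have been followed up by the study from these libraries, so its values are not independent evidence. Alternatives covered the pseudocount, the filter, scaling between libraries, a replicate block, library weights, the variance model, the threshold and each library left out. After the data had been seen, fits without 3 libraries that stood apart, with those libraries as a term, and without genes listed at 0 were added, together with tests of the direction-selective list without some of its members.

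The fit was tested on simulated data with the spread of the real libraries, in 10 simulations of 200 changed genes among the 11745. The changed genes were drawn only from genes with a mean above 4 on the log2(TPM + 1) scale. The recovery rates below therefore do not cover genes with lower means. For this comparison, 0% of genes changed 2-fold were recovered, 7.2% of those changed 4-fold, 46.8% of those changed 8-fold and 73% of those changed 16-fold, while 43 of 115344 unchanged genes were called. Of 10 simulated lists shifted by 1 log2 unit, camera called 7, with 1 other list called. The simulated genes varied independently of each other, which genes in the real libraries do not, so these rates do not carry over to the real lists. When the real libraries were divided otherwise than by genotype, camera called a median of 3 lists. Coordinates are from the GENCODE mouse release M21 annotation, which uses the same build as the deposited data. In that annotation 97.9% of the symbols were matched.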

Results

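The data set consisted of 10 RNA-seq libraries of Hb9-GFP retinal ganglion cells sorted at postnatal day 6, 5 from wild-type and 5 from Satb1 knockout mice. Hb9-GFP marks ganglion cells that respond to motion in a preferred direction (ON-OFF direction-selective ganglion cells), and Satb1 is a chromatin organizer and transcription factor. The question was which transcripts differ in these cells when Satb1 is missing. Between 10073 and 12556 genes per library had at least 1 TPM. Spearman correlations between libraries, taken across genes, ran from 0.513 to 0.81, with a median of 0.647 within a genotype and 0.649 between genotypes. The first principal component held 32.9% of the variance and set wild-type 5, knockout 4 and knockout 5 (scores of 88 to 149) apart from the other 7 libraries (at most -14.2). In those 3 libraries, cytosolic ribosomal protein genes took 12.2% to 13.7% of the TPM, against 3.88% to 8.04% in the other 7. Wild-type 4 stood apart on the second component, which held 13% of the variance, at a score of -145.

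**Figure D1:**
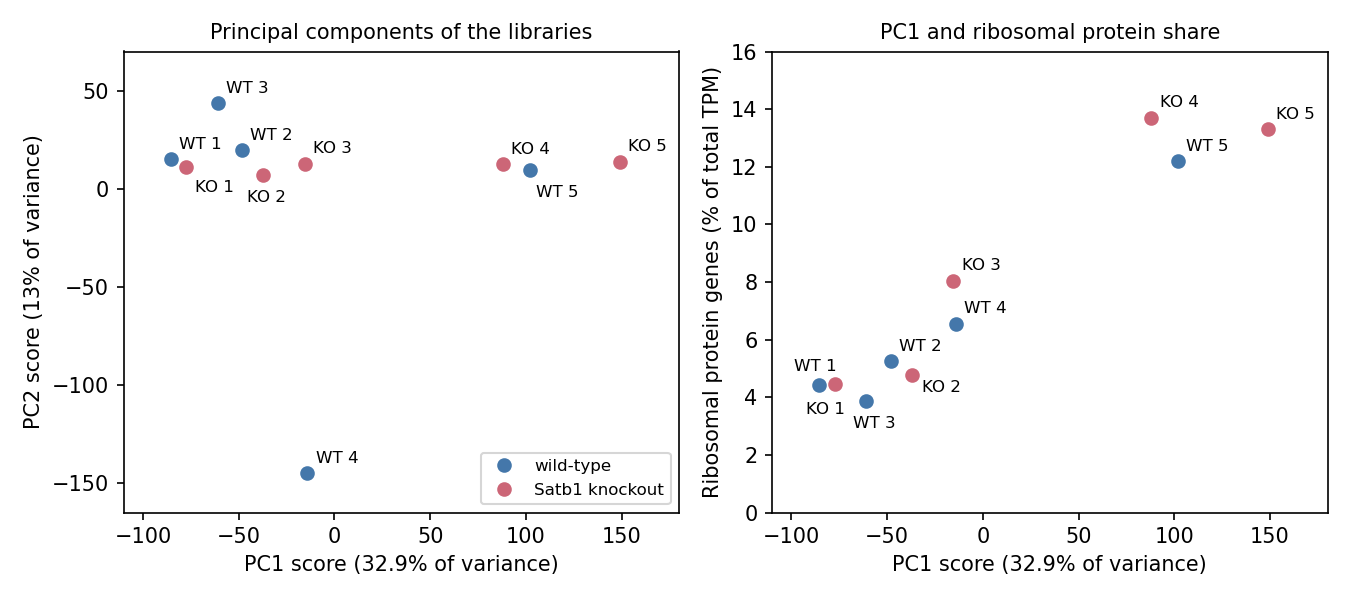
Left, scores of the 10 libraries on the first and second principal components, one point per library (WT, wild-type; KO, Satb1 knockout). Right, the share of total TPM in cytosolic ribosomal protein genes, in percent, against the first component; wild-type 5, knockout 4 and knockout 5 lie at 12.2% to 13.7% and the other 7 libraries at 3.88% to 8.04%.

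Satb1 transcripts (chromosome 17, 51736187 to 51833290, minus strand, mm10) were found in every library. Their level was 304, 189, 414, 132 and 38.6 TPM in wild-type 1 to 5, and 170, 126, 83.1, 34.9 and 24.1 TPM in knockout 1 to 5. The means were 216 ± 147 TPM in wild-type and 87.8 ± 61.6 TPM in knockout (SD, n = 5 each). The difference of -1.25 on the log2 scale (SE 0.71, 95% interval -2.73 to 0.23) was within the spread between replicates (two-sided exact permutation p = 0.135; limma, Benjamini-Hochberg adjusted p = 0.992). Which part of the gene is missing in the knockout is not stated in the labels, so a value for the whole gene checks the genotype only weakly. The lowest Satb1 levels of each genotype were in the 3 libraries apart on the first component.

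Several transcripts on the fixed list of direction-selective subtype genes had far lower mean levels in the knockout libraries. Of these, Cntn5 was followed up by the study from these libraries, so its place on the list may not be independent of them. Cartpt, which encodes a neuropeptide precursor (chromosome 13, 99898489 to 99901091, minus strand), stood at 481 ± 290 TPM in wild-type and 22.2 ± 18.1 TPM in knockout (SD, n = 5 each), a log2 difference of -4.49 (SE 0.82). Cntn5, which encodes the immunoglobulin-family adhesion protein contactin 5 (chromosome 9, 9660891 to 10904775, minus strand), stood at 49.7 ± 52.9 TPM and 2.23 ± 1.04 TPM, a difference of -3.38 (SE 0.81). For both genes, all 5 knockout libraries were below all 5 wild-type libraries. The matrix metalloproteinase gene Mmp17 (chromosome 5, 129584169 to 129611099, plus strand) went from 46.8 ± 48.5 to 7.86 ± 7.32 TPM (-2.24, SE 0.80). The transmembrane collagen gene Col25a1 (chromosome 3, 130131501 to 130599877, plus strand) went from 35.2 ± 30.2 to 2.60 ± 1.11 TPM (-2.49, SE 0.91). For both of these genes the genotypes overlapped. Mmp17 was at 20.5 TPM in knockout 4, above wild-type 1 and 2 (14.7 and 14.0 TPM), while the other 4 knockout libraries were below all wild-type libraries. Col25a1 was at 1.96 and 4.04 TPM in wild-type 4 and 5, against 1.67 to 4.025 TPM in knockout. In wild-type 1 to 3 it was at 47.5 to 67.2 TPM.

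Among the 9 preset genes, the two-sided exact permutation p was 0.00794 for Cartpt and for Cntn5, the smallest that the design allows, and 0.0357 for each after Benjamini-Hochberg adjustment over the 9. Cartpt passed this adjustment only through its tie with Cntn5, whose values are not independent evidence. For Mmp17 and Col25a1 the exact p values were 0.0238 and 0.0317, each 0.0713 after that adjustment. Over all 11745 genes the limma Benjamini-Hochberg adjusted p was 0.134 for Cartpt and 0.992 for Cntn5, Mmp17 and Col25a1, so none of the 4 passed across the transcriptome. Leaving out wild-type 4, which had the lowest wild-type level of Cartpt at 56.8 TPM, brought Cartpt to a limma adjusted p of 0.0287. That removal takes away the wild-type value nearest the knockout, and no other single library left out brought Cartpt past the threshold. Other markers of the same cells differed less than the spread between replicates. The cadherin gene Cdh6 stood at 159 ± 97.5 TPM in wild-type and 101 ± 53.8 TPM in knockout (-0.63, SE 0.60), and Fstl4 at 109 ± 95.2 and 64.8 ± 33.1 TPM (-0.52, SE 0.65). Mnx1, whose promoter drives the reporter, was low, at 0 to 8.04 TPM in wild-type and 0 to 4.44 TPM in knockout.

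**Figure D2:**
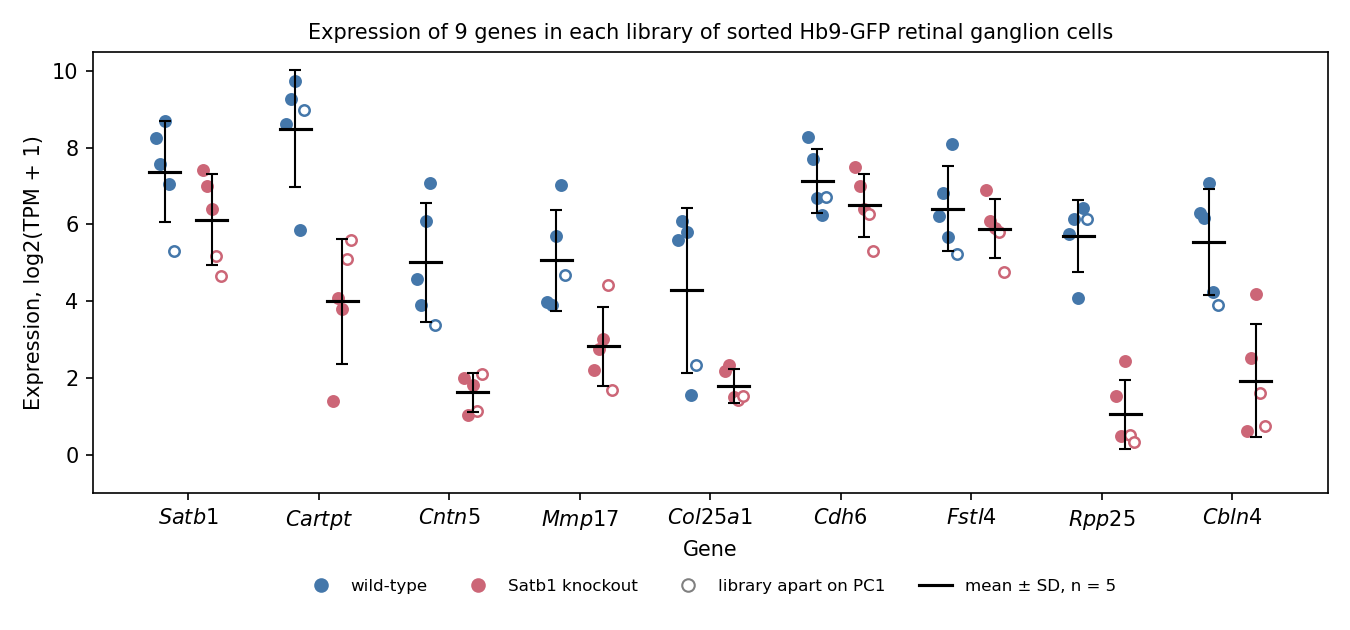
Expression of 9 genes on the log2(TPM + 1) scale in each library, with the mean and SD of the 5 libraries of each genotype; open points are wild-type 5, knockout 4 and knockout 5, the libraries apart on the first principal component. For Cartpt, Cntn5 and Rpp25 all 5 knockout points lie below all 5 wild-type points. The groups overlap for Satb1, Mmp17, Col25a1, Cdh6, Fstl4 and Cbln4.

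As a group, the list of direction-selective subtype genes fell relative to the other genes. Of its 12 tested members 10 were lower and 2 higher in knockout, where 67.4% of all tested genes were lower. After median centring 8 members were lower and 4 higher. The median log2 difference was -0.62 against -0.31 for all tested genes, and camera gave a Benjamini-Hochberg adjusted p of 0.00131 over the 34 lists. With an estimated correlation the adjusted p was 0.973. Adjusted over the list alone, 4 members passed and all 4 were lower: Cartpt (limma adjusted p = 0.000275), Cntn5 (0.00276), Mmp17 (0.0389) and Col25a1 (0.0389). Over all genes tested 0 of them passed, and since Cntn5 is the gene the study followed up from these libraries, its part is not independent evidence. The call rested on few members: the camera adjusted p was 0.0416 without Satb1 and Cntn5 and 0.193 without Cartpt and Cntn5. Without the 3 libraries apart on the first component it was 0.00406, with Cartpt and Cntn5 still passing over the list alone, as they also did with each library left out in turn. Mmp17 did not pass over the list (limma adjusted p = 0.0569 to 0.128) without wild-type 3 or 4 or knockout 1, 2, 3 or 5, and Col25a1 (0.0569 to 0.136) did not without any library but wild-type 4 or 5.

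Across all genes, limma called 0 of 11745 at a Benjamini-Hochberg adjusted p under 0.05, with 389 at an unadjusted p under 0.05 where 587 were expected by chance. Among the alternative fits, the count at an unadjusted p under 0.05 was above the expected number on leaving out wild-type 5 (845), with library weights (834) and with a replicate block (829). Of the 389, 87 were higher and 302 lower in knockout. This split depended on scaling: it was 234 higher and 149 lower after median centring, which moved the median difference of all genes from -0.31 to 0.07, and 189 higher and 212 lower after quantile normalization. Levels of the 5 knockout and 5 wild-type libraries did not overlap for 59 genes, 0.502% of those tested, against 0.794% by chance. The median SE of a log2 difference was 0.775, so differences of 2-fold to 4-fold in single genes were mostly not detectable here.

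The smallest p of all belonged to Rpp25, which encodes a protein subunit of ribonuclease P (chromosome 9, 57504026 to 57505448, plus strand). Its level was 58.5 ± 26.5 TPM in wild-type and 1.47 ± 1.76 TPM in knockout (SD, n = 5 each), a log2 difference of -4.65 (SE 0.76), with all 5 knockout libraries below all 5 wild-type libraries. Its limma Benjamini-Hochberg adjusted p of 0.0655 missed the threshold, and was 0.0413 without wild-type 3, the wild-type library with the lowest level. No other single library left out brought Rpp25 past the threshold. Cbln4, which encodes a secreted synapse organizer (chromosome 2, 172036233 to 172043466, minus strand), stood at 63.2 ± 49.7 and 5.04 ± 7.0 TPM (-3.61, SE 0.87). The mitochondrial ribosomal protein gene Mrpl47 stood at 38.1 ± 19.0 and 4.62 ± 2.80 TPM (-2.76, SE 0.71), and the proton pump subunit gene Atp6v0a2 at 9.09 ± 4.90 and 0.875 ± 0.594 TPM (-2.38, SE 0.65). Trim65 stood at 19.7 ± 16.1 and 0.858 ± 0.629 TPM (-2.97, SE 0.82). The somatostatin receptor gene Sstr4 was at 1.17 to 74.2 TPM in wild-type, and was listed at 0 in 4 knockout libraries and at 0.827 TPM in the fifth. The ceramide synthase gene Lass1 (Cers1) was at 1.04 to 144 TPM in wild-type and at 0 to 0.134 TPM in knockout. Ddt was at 8.33 to 175 TPM in wild-type and 0 to 16.6 TPM in knockout, Chchd8 (Coa4) at 5.45 to 43.0 and 0 to 19.1 TPM, and Hipk4 at 5.84 to 23.6 and 0 to 3.19 TPM. From Cbln4 to Hipk4 the limma Benjamini-Hochberg adjusted p was 0.992.

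In the other direction, the small Cajal body RNA Scarna3b was listed at 0 in 4 wild-type libraries and at 17.1 TPM in wild-type 5, and was at 15.1 to 33.8 TPM in knockout (log2 difference 3.95, SE 0.86; limma Benjamini-Hochberg adjusted p = 0.661). Without wild-type 5, the only wild-type library with a value above 0, the limma adjusted p was 0.0261. No other single library left out brought Scarna3b past the threshold. Scarna3b is a short RNA that such libraries measure poorly. The splicing factor gene Snrpa stood at 48.9 ± 26.7 TPM in wild-type and 174 ± 89.3 TPM in knockout (1.88, SE 0.62), and Mob3a at 3.22 ± 2.43 and 18.1 ± 9.18 TPM (2.28, SE 0.74). For both, all 5 knockout libraries were above all 5 wild-type libraries. Zfp703 stood at 1.28 ± 1.45 and 6.32 ± 2.51 TPM (1.80, SE 0.66), and Oraov1 (Lto1) at 3.87 ± 4.43 and 16.9 ± 8.21 TPM (2.15, SE 0.77). Brms1 was at 0 to 2.45 TPM in wild-type and 1.78 to 21 TPM in knockout, Krt28 at 0 to 1.40 and 0 to 33.2 TPM, and the mitochondrial import gene Timm50 at 0 to 25.9 and 10.6 to 133 TPM. Baiap2 was at 0 to 8.23 and 4.92 to 34.5 TPM, Rsph9 at 0 to 8.04 and 1.69 to 413 TPM, Pdia5 at 0 to 5.03 and 0 to 213 TPM, and Carns1 at 0 to 4.25 and 3.63 to 20.5 TPM. From Snrpa to Carns1 the limma Benjamini-Hochberg adjusted p was 0.992.

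Besides the direction-selective list, camera called 4 of the 34 lists at the preset correlation, and none of the 5 with an estimated correlation, where the adjusted p was 0.973 for each. Before adjustment, the camera p with an estimated correlation was 0.0299 for the direction-selective list and 0.123 to 0.406 for the other 4. Rod photoreceptor genes were higher relative to the other genes (11 of 14 members higher, median log2 difference 0.69, camera Benjamini-Hochberg adjusted p = 0.0278), although no member passed over the list alone. The mean log2(TPM + 1) of the rod list was 1.71, 2.15, 1.97, 4.74 and 5.39 in wild-type 1 to 5. In knockout 1 to 5 it was 4.46, 2.82, 5.04, 4.65 and 1.48, so the list was high or low by library in both genotypes. Pde6g, a phosphodiesterase subunit of phototransduction, was at 0, 1.56, 1.01, 192 and 189 TPM in wild-type 1 to 5 and at 182, 35, 217, 149 and 0 TPM in knockout 1 to 5, and Rcvrn (recoverin) was at 0, 2.46, 0, 17 and 44.7 TPM and at 0.31, 0, 6.16, 2.04 and 0.266 TPM. Leucine-rich repeat and teneurin synaptic adhesion genes were lower relative to the other genes (28 of 32 members lower, median -0.66, camera adjusted p = 0.0496). Elfn2 stood at 35.5 ± 16.3 TPM in wild-type and 9.05 ± 7.68 TPM in knockout and Slitrk6 at 19.9 ± 9.43 and 6.16 ± 7.56 TPM, and no member passed over the list alone. The rod call was lost on leaving out wild-type 1, 2 or 3 or knockout 1, 3 or 4 (adjusted p = 0.0976 to 0.583), and the adhesion call on leaving out any library but wild-type 5 or knockout 1 (0.0782 to 0.286). Without the 3 libraries apart on the first component the adjusted p was 9.87e-06 for rods and 0.0061 for the adhesion list, but with those libraries as a term both calls were lost (0.34 and 0.293). The rod call was also lost after median centring (0.137) and quantile normalization (0.235), and each of these lists was called in 10 of 24 alternative fits.

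Cytosolic ribosomal protein genes were higher relative to the other genes (50 of 75 members higher, median log2 difference 0.23, camera Benjamini-Hochberg adjusted p = 2.53e-06), as were nuclear-encoded oxidative phosphorylation genes (40 of 75 higher, median 0.07, adjusted p = 0.0278). Rpl34 had a log2 difference of 2.05 (SE 0.92) and Rps14 of 1.66 (SE 0.86), while Ndufs5 (-1.43, SE 0.72) and Atp5d (-0.96, SE 0.51) had the smallest p of the second list and went against its direction. Ribosomal protein genes took their largest shares of TPM in the 3 libraries apart on the first component, of which 2 were knockout. Without those libraries the medians were -0.12 and -0.32 and the camera adjusted p values 0.614 and 0.599. With them as a term the camera adjusted p values were 0.352 and 0.794, and after quantile normalization 0.165 and 0.644, while after median centring both lists passed (1.12e-05 and 0.0197). Of 24 alternative fits, 20 called the ribosomal protein list and 13 the oxidative phosphorylation list. Leaving out knockout 5 alone gave 0.297 and 0.931. The oxidative phosphorylation call was also lost without wild-type 1, 2, 3 or 4 or knockout 4, at 0.153 to 0.844.

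**Figure D3:**
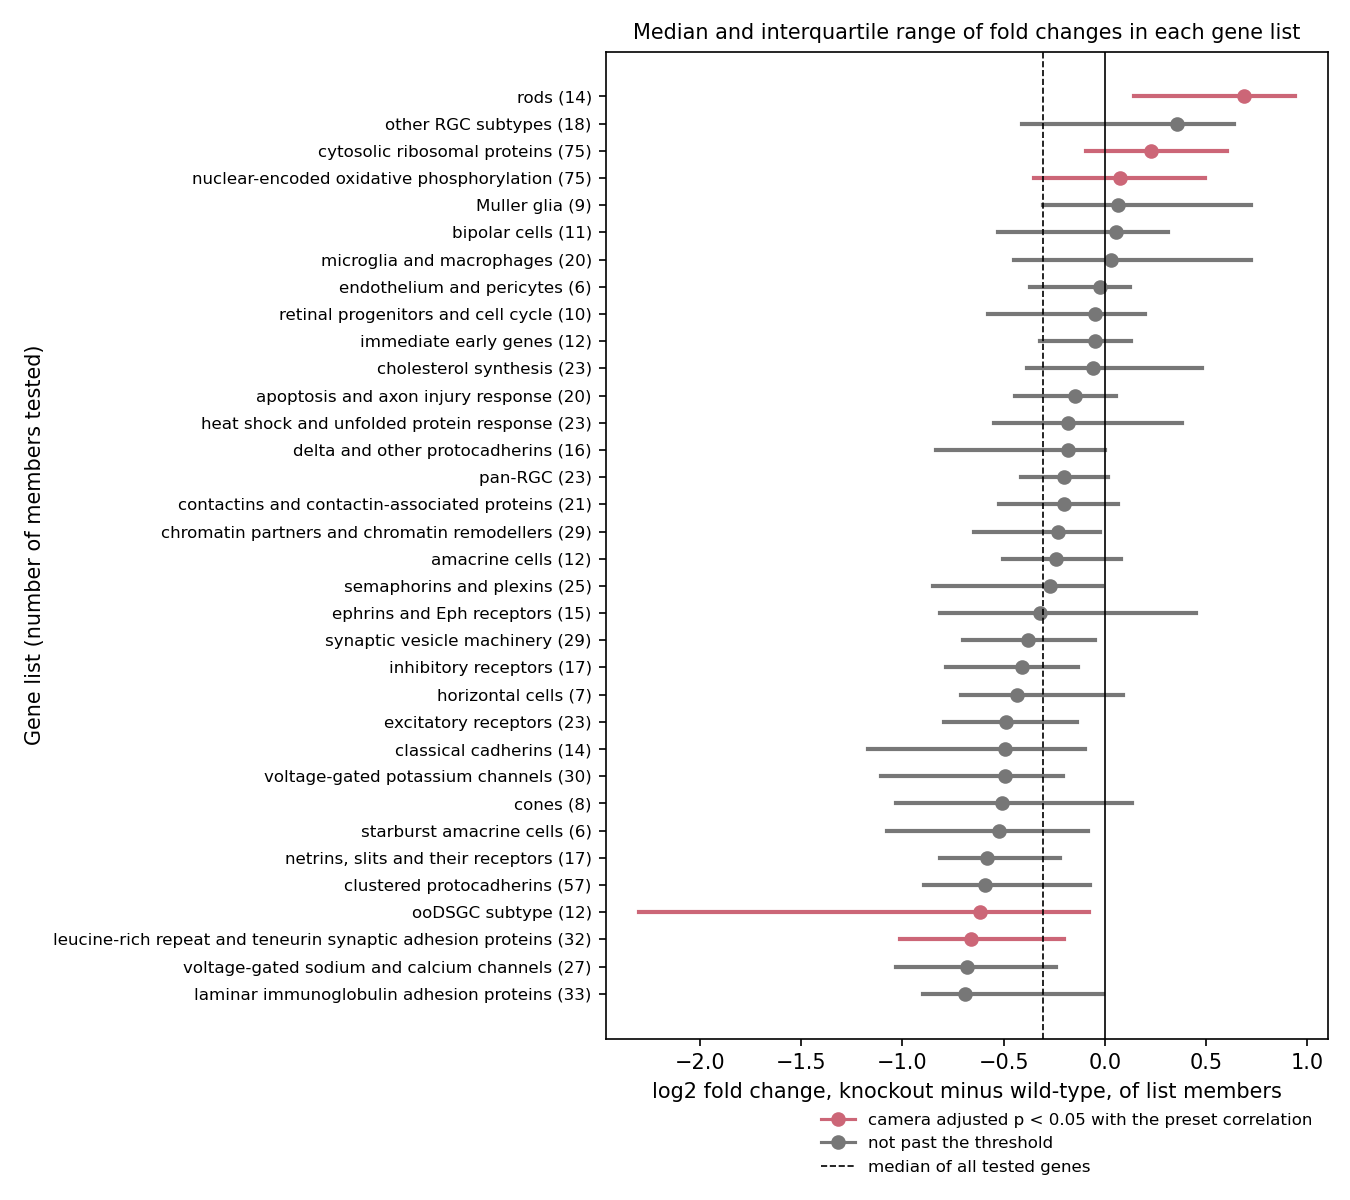
Median (points) and interquartile range (lines) of the log2 difference, knockout minus wild-type, over the tested members of each of the 34 lists, with the number of members in parentheses (RGC, retinal ganglion cell; ooDSGC, ON-OFF direction-selective ganglion cell); the dashed line is the median of all tested genes, -0.31. The 5 lists past the threshold at the preset correlation are in red; none passed with an estimated correlation.

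Markers of retinal cell types other than rods and direction-selective cells did not pass camera at a Benjamini-Hochberg adjusted p under 0.05. Pan-ganglion cell genes had 17 of 23 members lower and a median of -0.20 (adjusted p = 0.839), with Jam2 at 28.4 ± 19.2 TPM in wild-type and 13.7 ± 8.78 TPM in knockout and the synuclein gene Sncg at 2054 ± 1169 and 1332 ± 991 TPM. Markers of other ganglion cell subtypes had 10 of 18 members higher and a median of 0.36 (0.0739), and passed as higher without wild-type 4 (0.0108) and with library weights (0.0354), with adjusted p = 0.77 and 0.79 with an estimated correlation in those fits. The neuropeptide gene Npy, listed both there and among amacrine genes, stood at 465 ± 326 TPM in wild-type and 1002 ± 314 TPM in knockout (1.30, SE 0.54; limma adjusted p = 0.992), and the transcription factor gene Irx3 at 0 to 2.42 and 1.13 to 28.1 TPM. The medians were -0.24 for amacrine cells (0.973), where the glycine transporter gene Slc6a9 was at 2.03 to 19.2 TPM in wild-type and 0 to 1.60 TPM in knockout, and -0.52 for starburst amacrine cells (0.572). They were 0.05 for bipolar cells (0.65), -0.51 for cones (0.821), where the thyroid hormone receptor gene Thrb had a difference of -2.29 (SE 0.90), and -0.43 for horizontal cells (0.839). Muller glia had a median of 0.07 (0.193) and progenitor and cell cycle genes of -0.05 (0.729).

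Genes of cells that a sort can carry along were present at varied levels. Microglia and macrophage genes had 10 members higher and 10 lower, a median of 0.03 and a camera Benjamini-Hochberg adjusted p of 0.137, with Fcer1g at 35.9 ± 37.5 TPM in wild-type and 495 ± 616 TPM in knockout (2.89, SE 1.21). The list passed as higher relative to the other genes without wild-type 4 (camera adjusted p = 0.00013), knockout 1 (0.000489) or knockout 3 (0.0081), but not with an estimated correlation in those fits (adjusted p = 0.896, 0.808 and 0.935), so its call depended on single libraries, and it was at 0.837 without the 3 libraries apart on the first component. Endothelial and pericyte genes had a median of -0.02 (0.991). The pericyte gene Rgs5 passed over that list alone, where 6 genes were tested (limma adjusted p = 0.0348, and 0.992 over all genes), with 38.6, 42.9, 0, 23.8 and 3.18 TPM in wild-type 1 to 5 and 0.0326 to 1.59 TPM in knockout. That call was lost (limma adjusted p = 0.0528 to 0.117) without any single library but wild-type 3 or 5 or knockout 2, without the 3 libraries (0.167) and with them as a term (0.0891). Too few genes were tested for a set test of astrocytes (3), pigment epithelium (2) and blood cells (1), and 0 of the mitochondrial transcripts listed were found in the table. Of these lists' genes, Best1 of the pigment epithelium passed over its list alone (limma adjusted p = 0.0203, and 0.992 over all genes), at 0.137 to 18.3 TPM in wild-type and 0 to 2.41 TPM in knockout, and did not pass without wild-type 4 (0.0517), wild-type 5 (0.0601), knockout 5 (0.0524) or the 3 libraries (0.227). Aldoc of the astrocyte list stood at 39.6 ± 37.2 TPM in wild-type and 60.8 ± 49.6 TPM in knockout.

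Lists of adhesion and guidance genes had medians below 0 as deposited, which turned above 0 after median centring for contactins, delta and other protocadherins, semaphorins and ephrins. Apart from the leucine-rich repeat and teneurin list, none passed camera (Benjamini-Hochberg). For contactins and contactin-associated proteins the median was -0.20 (adjusted p = 0.839), and Cntn5 was the only one of 21 tested members past the threshold over the list alone (limma adjusted p = 0.00964). Among 33 laminar immunoglobulin adhesion genes the median was -0.69 (0.334), and again Cntn5 alone passed over the list (limma adjusted p = 0.0152), though not without wild-type 3 or 4 or knockout 2 (0.0504 to 0.0623). Cntnap2 stood at 82.2 ± 45.4 TPM in wild-type and 41.6 ± 42.8 TPM in knockout, and Dscaml1 at 26.1 ± 9.06 and 11.9 ± 12.3 TPM. Classical cadherins had a median of -0.50 (0.463), delta and other protocadherins of -0.19 (0.729), and clustered protocadherins, whose members share exons, of -0.59 (0.233). The median was -0.27 for semaphorins and plexins (0.729), -0.32 for ephrins and Eph receptors (0.973) and -0.58 for netrins, slits and their receptors (0.511). Epha10 stood at 182 ± 96.7 TPM in wild-type and 65.7 ± 67.4 TPM in knockout (-2.07, SE 0.84), and Pcdh10 at 249 ± 229 and 83.1 ± 64.0 TPM (-1.45, SE 0.75).

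Receptor, channel and synaptic genes likewise did not pass camera (Benjamini-Hochberg). The medians were -0.41 for inhibitory receptors (adjusted p = 0.354), -0.49 for excitatory receptors (0.403), -0.50 for voltage-gated potassium channels (0.181), -0.68 for voltage-gated sodium and calcium channels (0.148) and -0.38 for synaptic vesicle genes (0.219). The sodium and calcium channel list passed as lower without wild-type 5 (camera adjusted p = 0.0241) and with library weights (0.0331), with adjusted p = 0.836 and 0.79 with an estimated correlation in those fits. The GABA receptor subunit genes Gabrg3 and Gabra5 stood at 364 ± 256 and 142 ± 87.1 TPM in wild-type and at 124 ± 28.2 and 46.1 ± 19.1 TPM in knockout. The kainate receptor subunit gene Grik5 stood at 157 ± 88.7 and 52.9 ± 20.4 TPM, and the synapsin gene Syn2 at 61.9 ± 8.50 and 24.8 ± 13.7 TPM. Chromatin partners and remodellers had a median of -0.23 (0.947), with the insulator protein gene Ctcf at 38.6 ± 17.7 and 18 ± 9.98 TPM.

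Apart from the ribosomal protein and oxidative phosphorylation lists, stress and metabolic lists also did not pass camera (Benjamini-Hochberg). The medians were -0.05 for immediate early genes (adjusted p = 0.729), -0.15 for apoptosis and axon injury genes (0.729), -0.18 for heat shock and unfolded protein response genes (0.478) and -0.06 for cholesterol synthesis genes (0.193). Gadd45a stood at 1.42 ± 0.912 TPM in wild-type and 11.2 ± 12.1 TPM in knockout (1.71, SE 0.80), and the proapoptotic gene Bcl2l11 at 14.9 ± 13.4 and 3.52 ± 3.57 TPM (-1.67, SE 0.79). Directions of list medians depended on scaling: 27 of 34 were below 0 as deposited, 14 after median centring and 18 after quantile normalization, while the signs of the 5 called lists held in both. Since camera compares a list with the other genes, its direction was up for 7 lists whose median and mean were both below 0, namely pan-ganglion cell, horizontal cell, progenitor, endothelial, immediate early, apoptosis and heat shock genes, and for cholesterol synthesis, whose median and mean differed in sign. By fry, 0 lists passed for a shift on balance in one direction, and 1, the direction-selective list, passed for change in either direction (Benjamini-Hochberg adjusted p = 0.000122). That list holds Satb1 and Cntn5, and no fry result without them is given here. Since a few strongly changed members can carry such a test, its p is not independent of Cntn5.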

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

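The tests of transcript length, base composition, a few dominant genes and other divisions of the libraries were planned before their results were seen, and the tests of genotype on the first component, of the direction-selective genes and of their list over the divisions were chosen afterwards. Single libraries lay far from the other 4 of their genotype in 11 of 200 groups checked, where about 10 are expected by chance. The figures in this paragraph give the gap between the extreme library and its nearest neighbour as a share of the range. For genes the share was taken on the log2(TPM + 1) scale, while the levels in parentheses are in TPM. They were 0.716 for Cartpt in wild-type 4 (56.8 TPM, others 394 to 843), 0.82 for the second principal component in wild-type 4, and 0.757, 0.8 and 0.805 for Slitrk6, Hsph1 and Ctcf in wild-type 5, each low. For Scarna3b they were 1 in wild-type 5 (17.1 TPM, others at 0) and 0.768 in knockout 4 (15.1 TPM, others 28.1 to 33.8). The gap was 1 for Sstr4 in knockout 4 (0.827 TPM, others at 0) and 0.9 for Lass1 in knockout 3 (0.134 TPM, others up to 0.0126). For Sncg in knockout 4 it was 0.723 (3090 TPM, others 734 to 1090), and for Pcna in knockout 2 it was 0.806 (48.1 TPM, others 7.26 to 10.7).

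Wild-type 5, knockout 4 and knockout 5 lay at one end of the first principal component, and the scores differed between knockout and wild-type by 42.8 (95% interval -80.1 to 166, two-sided exact permutation p = 0.421), an interval too wide to tell whether genotype plays a part. The gap to the other 7 libraries was 43.8% of the component's range (95% interval over 100 resamplings of genes 41.7 to 45.6). It was 46.5% (41.6 to 51) after the trend with transcript length was removed and 33.6% (29.4 to 35.9) after the trend with GC content was removed. After the 50 highest genes were left out, TPM rescaled and the libraries centred on their medians, the gap was 56.4% (52.6 to 59.4). As far as each removal was complete, this argues against length, base composition or a few dominant genes, each alone, as the whole cause. The trends were removed separately and used the longest annotated transcript of each gene. A joint bias, or a bias that these transcripts miss, was not tested. The component held 32.9% of the variance as deposited, 25.1% without the length trend and 23% without the GC trend, and the gap in score units was 102, 87.1 and 65.6, so length and base composition may each account for part of the separation. Causes that the labels do not record, such as RNA quality, amplification yield or collection day, stay open and were not tested.

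Cartpt, Cntn5, Mmp17 and Col25a1 together averaged a log2 difference of -3.15 (95% interval -4.00 to -2.29), an interval that is too favourable because the 4 genes were picked for their low values. Without the 3 libraries apart on the first component the average was -3.58 (-4.63 to -2.53), which argues against those libraries as the cause. The 4 genes together with Cdh6 and Fstl4 are 6 of the 9 preset genes, but were chosen for this test after their values were seen. Their differences varied more than permuted labels gave after their shared difference was removed (SD 1.55 against a median of 0.84, exact permutation p = 0.0238, and 0.0317 without Cntn5). That choice makes the p too favourable, so it argues only weakly against a lower number of sorted cells of a kind that alone expresses all 6 genes. A loss of some direction-selective cells while the remaining cells express Cdh6 and Fstl4, and lower expression of the 4 genes per cell in the absence of Satb1, both stay open as hypotheses.

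Among 100 divisions of the 10 libraries into 5 and 5, the real one included, the highest other count of called genes was 581; with 0 called between genotypes all 100 reach the real count by construction, so for called genes the divisions decide nothing. Chance could not be excluded for the other counts. For genes at an unadjusted p under 0.05 the count was 389, 50 divisions reached it, and the highest other count was 3362, in a division that kept the 3 libraries together and so pointed to that structure of the samples. For lists passing camera the count was 5, 24 divisions reached it, and the highest other count was 14. For the direction-selective list, 1 of the 100 divisions, the real one, gave as small a camera p (7.68e-05 at the preset correlation, against 0.00542 as the smallest of the other divisions). The list was singled out from 34 after its result was seen and holds Cntn5, so this rank does not exclude chance.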

How the results depend on the processing

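The fits without the 3 libraries apart on the first component, with them as a term, and without genes listed at 0 were chosen after seeing the data; the other alternatives were planned. Log2 differences were recomputed for 92 genes named by the rule, not all of which are described here. Of 2194 recomputed values, 2184 kept their direction and their side of the threshold, 10 came past it and 0 reversed. Satb1 stayed between -1.77 and -0.80 and Cntn5 between -3.86 and -2.40 under every alternative, with limma adjusted p of 0.651 to 1 and 0.353 to 1. Against 0 genes called, 1 was called (Rpp25, lower) with a mean of at least 5 TPM, without the variance trend, with the robust fit, without genes listed at 0 and at an adjusted p under 0.1. Its limma Benjamini-Hochberg adjusted p was 0.0427, 0.0288, 0.046 and 0.0477 in the first 4, within 0.0205 to 0.799 over its alternatives. Library weights called 3, 1 higher and 2 lower: Cartpt (0.0149, range 0.0149 to 1), Rpp25 (0.0205) and Scarna3b (0.0205, range 0.0205 to 1). With each library left out, 0 to 1 genes were called, 0 to 1 higher and 0 to 1 lower: Rpp25 without wild-type 3 (0.0413), Cartpt without wild-type 4 (0.0287) and Scarna3b without wild-type 5 (0.0261). Against 5 lists, 3 were called without the filter, with a mean of at least 5 TPM, without the 3 libraries and without genes listed at 0, 2 after quantile normalization and after leaving out the highest genes, 1 with the 3 libraries as a term, 0 with an estimated correlation, 7 with library weights, and 2 to 6 with each library left out. The direction-selective list was among those called in 24 of 24 alternative fits at the preset correlation. The cause of these changes was not tested. The labels do not say that replicate numbers pair the libraries, and the values did not settle it: correlations of same-numbered libraries were 0.22, 0.074, 0.13, -0.03 and 0.36, 3 of 5 over 0.1, and 5 of 10 libraries correlated best with their own number. With the replicate block 0 genes and 4 lists were called (rods lost, camera adjusted p = 0.0564), 829 genes were at an unadjusted p under 0.05 against 389 without it, with Satb1 at -1.25 (unadjusted p = 0.015 against 0.0931 without it; limma adjusted p = 0.692) and Cntn5 at -3.38. Depth is unknown, so its effect on low values could not be assessed.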

Other observations

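Of the tests below, those of the microglia and macrophage genes were chosen after their values had been seen. Levels of Xist, expressed from the inactive X chromosome of females, and of the Y-linked gene Ddx3y differed between libraries in both genotypes. Xist was at 62, 178, 0.203, 0.0928 and 7.4 TPM in wild-type 1 to 5 and at 170, 0.599, 244, 90.7 and 0.00234 TPM in knockout 1 to 5. Ddx3y was at 15, 5.44, 10.5, 10.5 and 2.06 TPM in wild-type and at 32.1, 7.35, 0, 0.00506 and 1.78 TPM in knockout. Both transcripts were above 1 TPM in wild-type 1, 2 and 5 and in knockout 1. The melanopsin gene Opn4, a marker of another ganglion cell type, was at 85.1 TPM in knockout 4 and 61.6 TPM in knockout 5, and at 0 to 8.02 TPM in the other 8 libraries. The heme oxygenase gene Hmox1 was at 13900 TPM in knockout 5 and 1760 TPM in wild-type 4, and at 0.483 TPM in wild-type 3.

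Microglia and macrophage genes varied widely between libraries, although sorting on the reporter should leave such cells out. Tyrobp was at 192, 103, 0, 428 and 263 TPM in wild-type 1 to 5 and at 29.3, 545, 21.9, 82.8 and 1070 TPM in knockout 1 to 5, and C1qc ran from 1.59 TPM in wild-type 3 to 969 TPM in wild-type 4. The 20 listed genes, 0 of which stand in another list, varied together: their median pairwise Spearman correlation over the 10 libraries was 0.648, against a median of 0.121 and a 95th percentile of 0.303 in 10000 random lists matched on size and level. RNA from microglia or macrophages in the sorted material is a candidate explanation that this value fits, and Ctss of the list is also expressed by many other cells. Whether the list differs with genotype cannot be told: the knockout minus wild-type difference of its mean was 0.15 on the log2 scale (95% interval -2.65 to 2.96, two-sided exact permutation p = 0.921), and spread between libraries keeps it open.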
